A study of Homo sapiens with 6 samples.

How the data were processed

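Expression was measured in 6 preparations of CAL-51, an established human breast cancer cell line. Per the labels, cells of 3 consecutive culture passages were stained with the dye H33342 and sorted by flow cytometry into side population (SP) and non-side population (NSP) cells. Total RNA was purified with RNeasy, and biotinylated cRNA made from it was hybridised to Affymetrix HG-U133 Plus 2.0 arrays, 1 array per preparation, per the labels' protocols. The passages come from 1 cell line, so p-values measure the spread between these preparations and not between tumours.

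The deposited values are an intensity for each probe set on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version and settings are not given in the sources used here. The trimmed mean of the signals, leaving out 2% on each side, was 150.0 on every array, so the arrays had been scaled globally to a common target before deposit. A signal near the array medians of 32.0 to 35.1 lies close to background. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.26.

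Group and replicate number were taken from the sample titles, which name 3 SP and 3 NSP arrays. The values were used without another normalization. The 62 control probe sets were left out, 16 was added to each signal, and log2 was taken. Fold changes are therefore on the log2(signal + 16) scale, which understates the change of dim genes. The upper 50% of the probe sets by mean log2 value over all 6 arrays, was tested, which left 27306 probe sets with a mean signal above about 30.0. The contrast SP minus NSP was fitted with lmFit and eBayes(trend = TRUE) of limma 3.58.1 in R 4.3.3, with a two-sided test and Benjamini-Hochberg adjustment over all tested probe sets at a threshold of 0.05. Probe sets past this threshold are called changed. Every adjusted p of a gene or probe set comes from this limma fit unless another is named.

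Gene symbols came from the platform annotation, updated through the names of the RefSeq gene table, which was used for names only because no genome build is named for these arrays. Of 54675 probe sets, 41091 had 1 symbol, 1801 had several and 11721 had none besides the 62 controls. The 41091 probe sets with 1 symbol covered 19775 genes, and for 54 of these probe sets no match was found and the symbol of the annotation was kept. Probe sets without a symbol are unnamed here, which does not mean that they lie outside genes. Each gene was represented by its brightest tested probe set with exactly 1 symbol, giving 12240 genes, and some other probe sets that differ are named.

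Before the data were examined, 25 gene lists with 667 distinct genes were fixed. They cover ABC transporters, stem cell factors, endoderm factors, interferon-stimulated genes, G1/S and DNA replication genes, G2/M genes, histone genes, immediate-early and short-lived transcripts, heat shock genes, endoplasmic reticulum and integrated stress genes, hypoxia and glycolysis genes, cholesterol synthesis genes, epithelial genes, mesenchymal genes, luminal breast genes, basal breast genes, blood cell markers, Wnt target genes, Notch target genes, TGF-beta and BMP target genes, NRF2 and AHR target genes, NF-kB target genes, ribosomal protein genes and oxidative phosphorylation genes. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 25 lists. Camera with an estimated correlation and fry (statmod 1.5.0) were run as alternatives. An estimated correlation below the preset 0.01 cannot by itself cost a list its call. For members of a list, p-values were also adjusted over the list alone.

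The genes named in the text follow a rule fixed before the data were examined. It took candidates chosen for the side population gate and this cell line, up to 12 genes with the largest rise and 12 with the largest fall among changed genes whose groups did not overlap, and up to 4 members of each list with the smallest p. A side with fewer than 5 such genes was filled to 8 with the smallest unadjusted p among non-overlapping genes with a log2 fold change of at least 1 in size, given as values only. The candidates were SOX17, ABCG2, ABCB1, ABCC1, TOP1, TOP2A, CDKN1A, OAS1 and MX1. SOX17 was chosen because what was known of the study linked it with the SP of this line, so it was not an independent choice. A further candidate, 1 of the 25 lists and some control probe sets are not reported here.

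RNA quality was read from the 3' and 5' control probe sets of GAPDH and ACTB, compared by two-sided exact permutation tests of 3 against 3 arrays, whose smallest possible p is 0.1. The procedure was tested on simulated data for SP against NSP, over 27306 probe sets with independent noise. It recovered 23.5% of the probe sets changed by a log2 fold change of 1, 78.8% at 1.5 and 97.0% at 2, with 6 false calls among 138, and made 1 call in unchanged arrays. On the real arrays genes of some lists moved together and NSP replicate 3 stood apart, so these rates need not hold for the data.

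The alternatives were pseudocounts of 1 and 64, no filter, the upper 25% of probe sets, quantile normalization, centring of each array on its median, the replicate number as a block, no trend or a robust variance prior, leaving out cross-hybridising probe set types, each array left out in turn, the mean of the probe sets of a gene, and an adjusted p under 0.10 or a fold change of at least 2. After the data were examined, a fit without both arrays of replicate number 3 and a fit with the log2 GAPDH 3' to 5' ratio as a covariate were added. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.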

Results

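CAL-51 cells that export the DNA dye H33342 appear dim in flow cytometry and form the side population (SP), a gate often used to enrich stem-like cells. Cells that keep the dye form the non-side population (NSP). RNA of both fractions from 3 passages was measured on 6 arrays, 3 of SP and 3 of NSP cells, to find the genes whose expression differs between them. Array medians lay between 32.0 and 35.1 signal units, and the 2% trimmed mean was 150.0 on each array.

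RNA quality was uneven. The GAPDH 3' to 5' signal ratio was 1.37, 1.59 and 6.26 on NSP replicates 1, 2 and 3, and 1.85, 1.90 and 1.84 on the SP replicates. The ACTB ratio was 10.9, 11.1 and 25.2 on the NSP arrays and 15.7, 14.2 and 11.5 on the SP arrays. Neither ratio differed between the groups beyond the spread (two-sided exact permutation p = 1 for both), because NSP replicate 3 stood above all SP arrays and the other NSP arrays below them. The first principal component, with 40.7% of the variance, set NSP replicate 3 apart, with a score of 85.7. SP replicate 3 came next at 8.4, and the remaining arrays lay between −27.2 and −15.7.

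**Figure D1:**
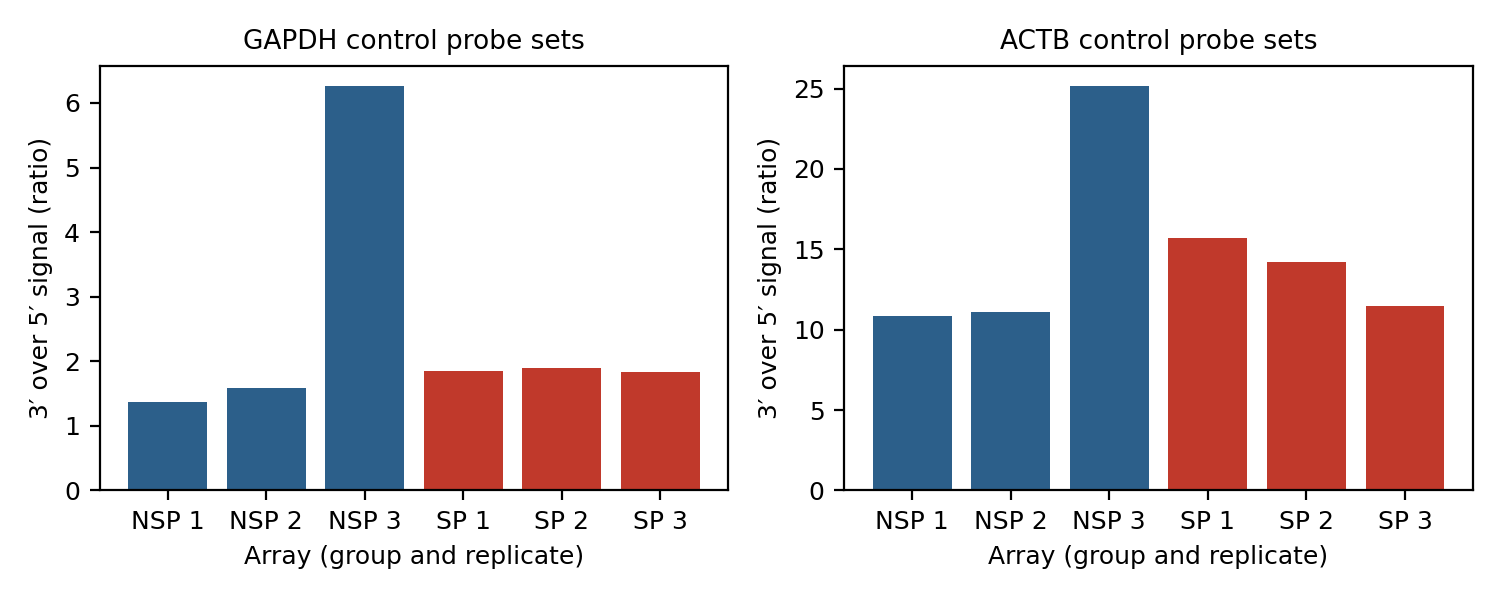
Ratio of the 3' to the 5' control probe set signal (no unit) for GAPDH (left) and ACTB (right) on each of the 6 arrays, with 1 bar per array, NSP in blue and SP in red. NSP replicate 3 has the highest ratio in both panels, 6.26 for GAPDH and 25.2 for ACTB.

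SP cells carried more RNA of 10 genes than NSP cells, and no gene passed the test in the other direction. SOX17, a transcription factor of endoderm formation, had a signal of 1112 ± 149.9 (SD, n = 3) in SP and 358 ± 66.4 in NSP cells, a log2 fold change of 1.60 ± 0.21 (SE; limma adjusted p = 0.0428). The inflammatory genes IER3, an early-response gene, and CXCL2, a neutrophil chemokine, rose by 1.86 ± 0.19 and 1.82 ± 0.19 on the log2 scale (limma adjusted p = 0.0372 for both). BCL2L11, which encodes the pro-apoptotic protein BIM, rose by 1.46 ± 0.20 (limma adjusted p = 0.0428).

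The other 6 genes that rose were MYLIP, EPC1, YPEL2, INTS6, ARID4B and ZFP36L2. MYLIP, the ubiquitin ligase that degrades the LDL receptor, had the largest log2 fold change of the 10, 1.89 ± 0.24, with signals of 884.8 ± 212.3 in SP and 224 ± 34.0 in NSP cells (limma adjusted p = 0.0417). EPC1, a subunit of the NuA4 histone acetyltransferase complex, rose by 1.70, and ARID4B, a subunit of the SIN3 deacetylase complex, by 1.30. INTS6, a subunit of the Integrator complex, rose from 243.9 ± 21.9 in NSP to 715.6 ± 29.9 in SP cells, and YPEL2 rose by 1.60. ZFP36L2, which destabilises mRNAs with AU-rich elements, was among the brightest, at 4433 ± 504.5 in SP and 1800.1 ± 162 in NSP cells, a rise of 1.29. In each of the 10 genes all 3 SP arrays lay above all 3 NSP arrays, and the exact permutation p of 0.1 is the smallest that 3 against 3 arrays allow.

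Other probe sets of these genes did not all move as far. The second SOX17 probe set showed a log2 fold change of 1.79 ± 0.38 (limma adjusted p = 0.131) with no overlap between the groups. The second YPEL2 probe set gave −0.28 ± 0.39, and 2 of the 6 BCL2L11 probe sets had negative values, −0.12 and −0.23. CXCL2 and IER3 each rested on 1 tested probe set. The fit without cross-hybridising probe set types left out those with the suffixes _x_at and _s_at. The probe set used for CXCL2 is an _x_at one, and those for IER3, MYLIP, EPC1 and ARID4B are _s_at ones. Whether any of them cross-hybridises was not tested.

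No gene fell. The 8 genes named in the lower direction, those with the smallest unadjusted p among genes at least 2-fold lower without overlap, are given as values. TENT5B showed −1.48 ± 0.23 (limma adjusted p = 0.0577) and TCEAL7 −1.48 ± 0.25 (limma adjusted p = 0.0759). With the replicate number as a block both passed as lower in SP cells (limma adjusted p = 0.0491 and 0.0367). CCN2, a secreted matricellular protein and YAP target, had signals of 943.5 ± 201 in SP and 2001 ± 268 in NSP cells, −1.09 ± 0.22 (limma adjusted p = 0.119). For the kinase SGK1 and the actin regulator VASP the log2 fold changes were −1.04 and −1.01 (limma adjusted p = 0.131 and 0.141). The last 3 were CYP27A1 with −1.35, NANOS1 with −1.10 and LINC00957 with −1.17, at limma adjusted p between 0.176 and 0.187.

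**Figure D2:**
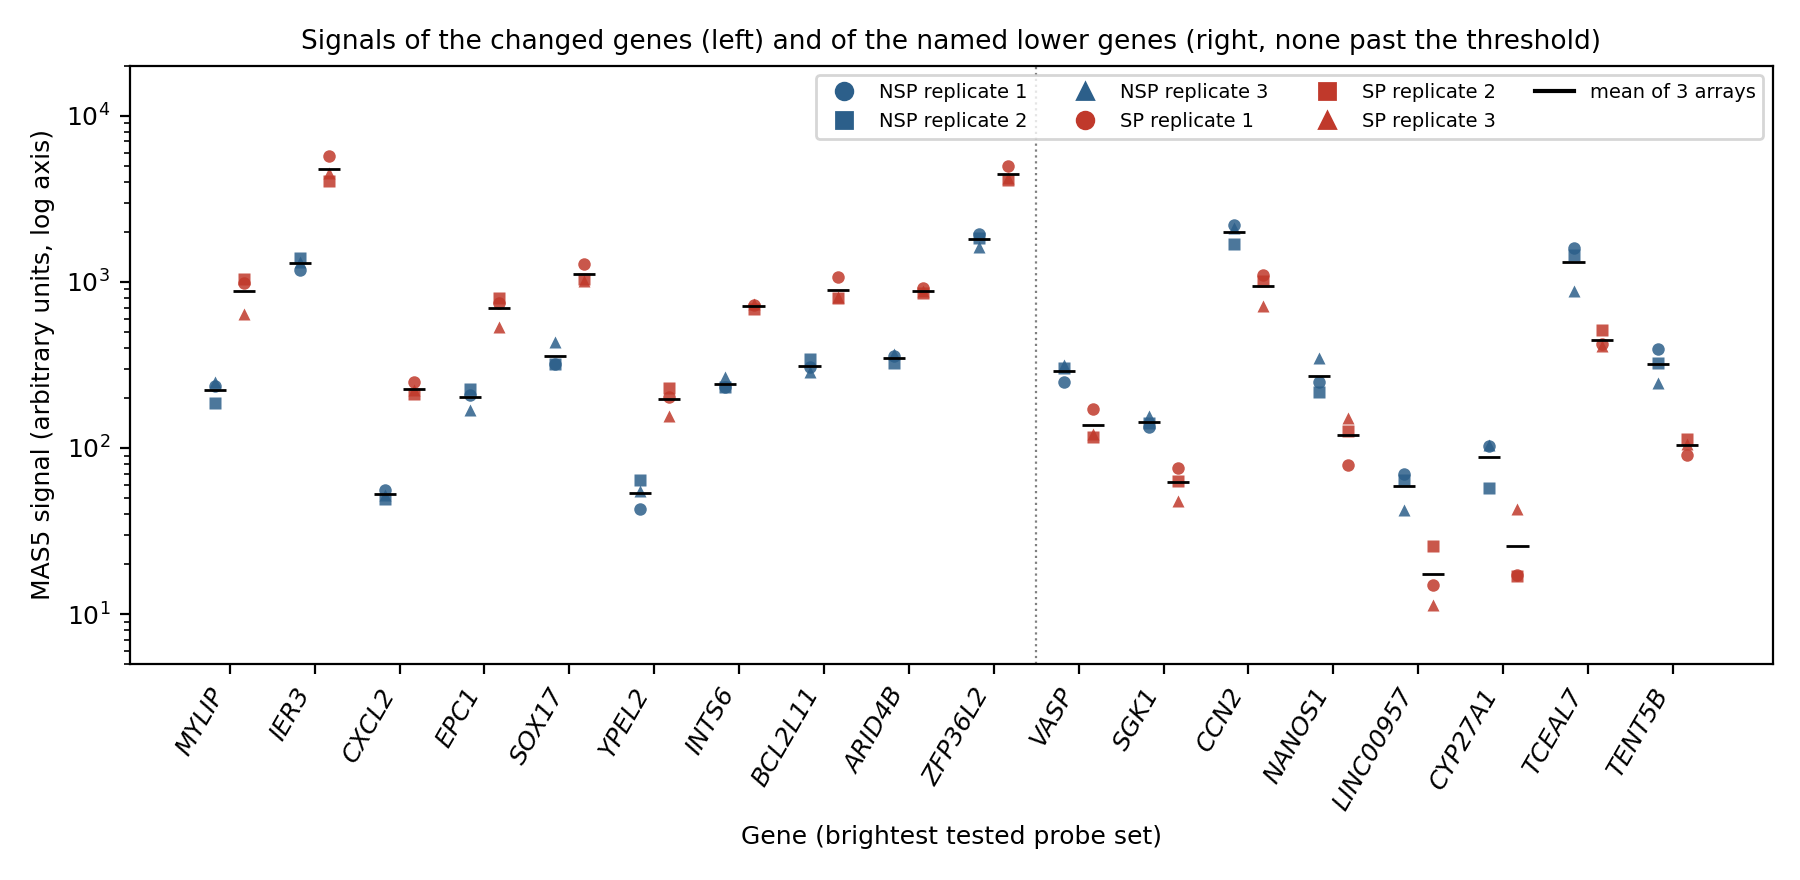
MAS5 signal (arbitrary units, log axis) of the 10 changed genes, left of the dotted line, and of the 8 named lower genes, right of it. None of the 8 passed the threshold in the fit without a block. Each point is 1 array, NSP in blue and SP in red, with a symbol per replicate number, and black lines are means of 3 arrays; for every gene shown the groups do not overlap.

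Over all 27306 tested probe sets, 39 were higher in SP cells and 0 lower at an adjusted p under 0.05 in limma, with folds of 2.45 to 5.30. At an unadjusted p under 0.05 there were 2240 higher and 835 lower, a split that became 1780 and 1159 after quantile normalization and 1441 and 1750 after centring each array on its median. The median log2 fold change of the tested probe sets was 0.03, −0.02 and −0.08 under these 3 scalings. Groups did not overlap for 18.4% of the genes, against 10% by chance. The count of 39 was 239 (209 higher, 30 lower) without NSP replicate 3, 1 without SP replicate 3, and 0 without any 1 of NSP replicates 1 and 2 and SP replicates 1 and 2; it was also 0 with no filter or no variance trend, 17 after quantile normalization and 7 after median centring.

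Among the candidates tied to the SP gate, neither dye exporter passed. ABCG2, an exporter of H33342, had signals of 40.9 ± 15.7 in SP and 22.8 ± 16.5 in NSP cells, a log2 fold change of 0.61 ± 0.41 (limma adjusted p = 0.733 in the fit without the filter). ABCB1 was dimmer still, with 21.3 ± 9.41 and 11.3 ± 13.1 and a log2 fold change of 0.52 ± 0.37 (limma adjusted p = 0.753 without the filter). A second ABCB1 probe set gave 0.80 ± 0.35, at 20.2 ± 20.1 in SP and 2.87 ± 0.90 in NSP cells with no overlap (limma adjusted p = 0.571 without the filter). Both genes lie close to background, where a difference is hard to detect. ABCC1, at 775.4 ± 84.4 and 707.5 ± 276.1, gave 0.19 ± 0.27 (limma adjusted p = 0.838). The topoisomerases TOP1 and TOP2A, both of which can be targets of DNA-binding dyes, gave −0.03 ± 0.19, a sign that turned under quantile normalization, and −0.48 ± 0.61 (limma adjusted p = 0.965 and 0.813), while dimmer probe sets gave 0.10 for TOP1 and −0.34 and 0.27 for TOP2A. The TOP2A signals were 1918.3, 2734.3 and 474.2 on SP replicates 1 to 3 and 2721, 2519.9 and 1013.5 on NSP replicates 1 to 3. Its negative sign rested on SP replicate 3. CDKN1A, a cell cycle inhibitor, gave 0.35 ± 0.23 (limma adjusted p = 0.625), and the interferon-induced genes OAS1 and MX1 were near background at 25.7 against 12.8 and 10.8 against 17.9.

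Genes of cell division leaned lower in SP cells as groups, in calls that did not hold with an estimated correlation (adjusted p = 0.658 with an estimated correlation for G1/S and 0.763 with an estimated correlation for G2/M). In the G1/S and DNA replication list 27 of 33 measured genes had a negative log2 fold change, with a median of −0.39 (camera adjusted p = 4.09e-05). In the G2/M list it was 25 of 32, with a median of −0.29 (camera adjusted p = 0.0249). CDC6, a replication licensing factor, had signals of 181.9 ± 28.4 in SP and 338.8 ± 108.5 in NSP cells, and CDK1, the mitotic kinase, 1176 ± 450.9 and 2156 ± 475.9. No member of either list passed the test over all probe sets or adjusted over the list alone.

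The genes within these lists moved together across arrays, with estimated correlations of 0.74 and 0.92. NSP replicate 3, the array with the GAPDH ratio of 6.26, had a mean log2 signal of 9.22 for the G1/S list against 10.14 and 10.20 on NSP replicates 1 and 2 and 9.56, 9.75 and 9.31 on the SP arrays. For the G2/M list NSP replicate 3 was at 8.66 and SP replicate 3 at 8.36, with the other 4 arrays between 9.76 and 10.13. Without NSP replicate 3 the medians were −0.70 for G1/S and −0.74 for G2/M (camera adjusted p = 2.53e-15 and 6.07e-08), and both calls were lost there too with an estimated correlation (adjusted p = 0.548 and 0.604 with an estimated correlation). The G1/S median was −0.19 without NSP replicate 1, −0.26 without SP replicate 3 and −0.23 without NSP replicate 2, where its call ended (camera adjusted p = 0.0611). The G2/M median was −0.07 without NSP replicate 1, −0.09 without NSP replicate 2, −0.47 without SP replicate 1 and −0.56 without SP replicate 2; the G2/M call ended without NSP replicate 1 or 2 or SP replicate 3, where its median turned to 0.17, and after quantile normalization or median centring (camera adjusted p = 0.0920 and 0.0593).

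Oxidative phosphorylation genes leaned lower in SP cells and cholesterol synthesis genes higher, in calls that did not hold with an estimated correlation (adjusted p = 0.350 with an estimated correlation for each list). The estimated correlations were 0.14 and −0.00046, far below those of the cell division lists. The cholesterol call passed in 19 of its 21 alternatives and was lost with an estimated correlation and with fry (fry adjusted p = 0.0644). Of 43 measured respiratory chain and ATP synthase genes 40 were lower, with a median of −0.20 (camera adjusted p = 4.09e-05). The ATP synthase subunit ATP5MC1 had signals of 992.3 ± 192.3 in SP and 1487 ± 120.6 in NSP cells, and cytochrome c (CYCS) 4938 ± 438.2 and 6665 ± 778.9. Of 18 cholesterol synthesis genes 17 were higher, with a median of 0.36 (camera adjusted p = 0.00187). HMGCS1, which makes HMG-CoA, the precursor of mevalonate, was at 1258 ± 70.1 in SP and 614.9 ± 200.1 in NSP cells, a log2 fold change of 1.06 ± 0.24, and TM7SF2, a sterol reductase, gave 1.32 ± 0.42. On NSP replicate 3 TM7SF2 was lowest, at 105.3 against 372 and 394.3 on NSP replicates 1 and 2. HMGCS1 was highest there, at 843.3 against 530.9 and 470.5.

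In both lists 0 members passed over all probe sets (limma, with 2 lower and 5 higher at an unadjusted p under 0.05), and adjusted over the list alone 0 passed among oxidative phosphorylation genes and 1, HMGCS1, rose among cholesterol genes. Without NSP replicate 3 the medians were −0.20 and 0.36 and both lists passed, but not with an estimated correlation (adjusted p = 0.548 with an estimated correlation for each). The call of the oxidative phosphorylation list ended after quantile normalization, where its median was −0.07 (camera adjusted p = 0.131).

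Basal breast genes leaned lower and Wnt target genes higher in SP cells, in calls that did not hold with an estimated correlation (adjusted p = 0.350 with an estimated correlation for each) or in several other settings. The basal list had 5 measured members, 3 of which fell adjusted over the list alone, 0 over all probe sets, with a median of −0.64 (camera adjusted p = 0.0249) that was −0.04 with no filter (0.569). CAV1 and CAV2, which form caveolae, were at 2995 ± 437.5 and 1218 ± 247.5 in SP cells and at 5312 ± 1712 and 2215 ± 835.8 in NSP cells, and the calcium-binding protein S100A2 gave −0.64 ± 0.19, while the receptor EGFR gave 0.12 ± 0.21, and −0.68 to −0.20 on its 4 dimmer probe sets. The Wnt list of 11 genes had a median of 0.30 (camera adjusted p = 0.0447), and 0 members passed either way. That median was 0.12 in the upper 25% of probe sets, 0.45 without NSP replicate 1, 0.50 without SP replicate 1 and 0.53 without NSP replicate 2. ZNRF3, a feedback inhibitor of Wnt receptors, was at 0.71 ± 0.21. SOX4 was at 0.99 ± 0.42, with 1.28 to 2.59 on its 3 dimmer probe sets. Both calls were lost without NSP replicate 3 (camera adjusted p = 0.0761 for basal and 0.212 for Wnt genes), without SP replicate 1 (0.0753 and 0.0530) and after quantile normalization (0.0548 and 0.0733). The Wnt call also ended without NSP replicate 2 (0.119), without SP replicate 2 (0.0729), in the upper 25% of probe sets (0.171) and without cross-hybridising probe set types (0.0807). The estimated correlation of the Wnt list was −0.018, below the preset 0.01, so correlation between its genes does not account for the loss with that setting.

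**Figure D3:**
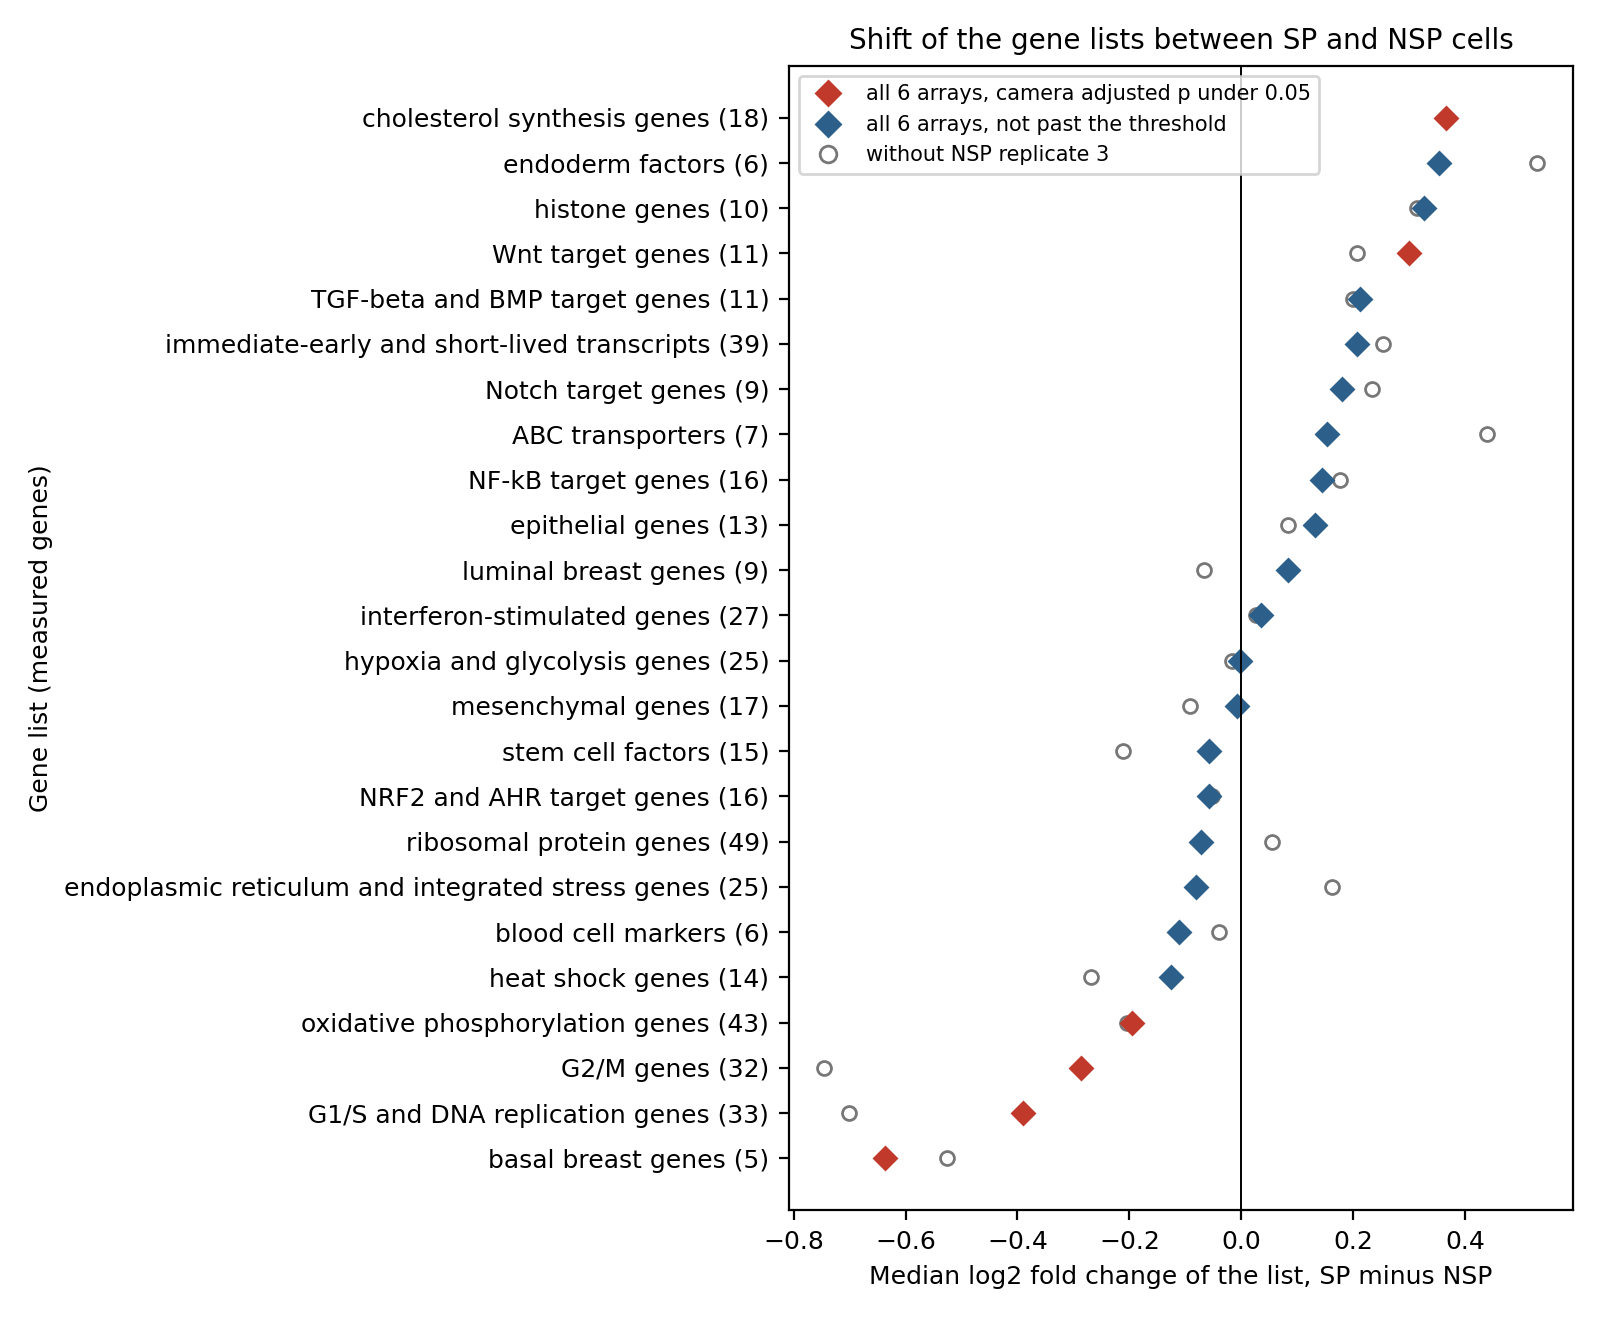
Median log2 fold change, SP minus NSP, of each gene list reported, with the number of measured genes in brackets; diamonds use all 6 arrays, red for a camera adjusted p under 0.05, and open circles leave out NSP replicate 3. The G1/S and G2/M medians lie at −0.39 and −0.29 with all arrays and at −0.70 and −0.74 without NSP replicate 3.

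Immediate-early and short-lived transcripts moved in both directions. Of 39 measured genes 2 rose over all probe sets, IER3 and ZFP36L2, and 0 fell; adjusted over the list alone 9 rose and 5 fell. Next to the 2 that rose stood the MAP kinase phosphatase DUSP6, at 4628 ± 373.6 in SP and 2156 ± 138.7 in NSP cells (1.10 ± 0.17, limma adjusted p = 0.0576), and the growth factor signalling inhibitor SPRY2, with 1.07 ± 0.20 (limma adjusted p = 0.1003). Both passed with the replicate number as a block (limma adjusted p = 0.0443 and 0.0495). CCN2 and SGK1 belong to this list too and lay lower in SP cells. The list as a whole had a median of 0.21 and missed the threshold (camera adjusted p = 0.0858, and adjusted p = 0.350 with an estimated correlation), and it passed without NSP replicate 3 with a median of 0.25 (camera adjusted p = 0.0385, but adjusted p = 0.548 with an estimated correlation). It also passed without NSP replicate 1 (0.0422), with no filter (0.0282), in the upper 25% of probe sets (0.00128) and after median centring (0.0438), but its median was 0.12 without SP replicate 3 (0.284) and 0.14 without cross-hybridising probe set types (0.514). In fry's test for changes in either direction it passed, with adjusted p = 0.000218, as did the NF-kB, endoderm and mesenchymal lists. The NF-kB and endoderm lists each held 1 changed gene, CXCL2 and SOX17, and whether they pass without it was not tested.

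Signalling and developmental lists held single genes that stood out. Among 6 endoderm factors 1 rose, SOX17, and adjusted over the list alone 2 did, SOX17 and the chemokine receptor CXCR4 (1.06 ± 0.31, but 0.02 ± 0.32 on its second probe set), with a list median of 0.35 (camera adjusted p = 0.0874). The median was 0.04 with no filter, 0.13 without NSP replicate 2, 0.16 without SP replicate 1, 0.53 without NSP replicate 3 and 0.65 without SP replicate 3. Among 16 NF-kB target genes 1 rose, CXCL2, by either adjustment, with a median of 0.14 (camera adjusted p = 0.359) that was 0.06 without SP replicate 1, 0.08 without SP replicate 3 and −0.01 without SP replicate 2. Among 9 Notch target genes 0 passed and 1, HES1, rose adjusted over the list alone (0.93 ± 0.23), with a median of 0.18 (camera adjusted p = 0.0837). Among 11 TGF-beta and BMP target genes 0 passed and 2 rose adjusted over the list alone, the inhibitors BAMBI (0.84 ± 0.19) and SMAD7 (0.85 ± 0.22), with a median of 0.21 (camera adjusted p = 0.411). Among 17 mesenchymal genes 0 passed, and adjusted over the list alone the transcription factor TWIST1 (1.06 ± 0.21) and the matrix protein FN1 (0.82 ± 0.24) rose and the collagen cross-linking enzyme LOX fell by 0.80 on the log2 scale; the median was −0.0071, the mean 0.12 and camera's direction up (adjusted p = 0.662). The endoderm list passed without SP replicate 3 (camera adjusted p = 0.0240), and the Notch list without SP replicate 3 or NSP replicate 1 (0.0244 and 0.0400), but with all arrays adjusted p = 0.350 with an estimated correlation for each. The Notch median was 0.31 without NSP replicate 1, and the TGF-beta median 0.14 without SP replicate 2. The mesenchymal median turned to 0.11, 0.06 and 0.08 without NSP replicate 2, SP replicate 1 and SP replicate 3 and was −0.09 without NSP replicate 3.

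Stem cell and transporter lists did not pass. Among 15 stem cell factors 0 passed by either adjustment, with a median of −0.06, a mean of 0.05 and camera's direction down (adjusted p = 0.697). That median was −0.21 without NSP replicate 3, −0.15 without SP replicate 2, −0.10 without NSP replicate 1 and −0.03 without SP replicate 1, and without SP replicate 3 it turned to 0.06 with camera's direction up. NES, an intermediate filament protein of neural progenitors, gave 1.02 ± 0.38, and KLF4, a reprogramming factor, was at 117 ± 15.3 in SP and 219.8 ± 105.1 in NSP cells. Among 7 ABC transporters 0 passed by either adjustment, with a median of 0.15 (camera adjusted p = 0.775), ABCA3 at 0.44 ± 0.24 and ABCC4 at −0.46 ± 0.30. The ABCC4 signal was 1667.3 on NSP replicate 3 against 854.4 and 910.3 on NSP replicates 1 and 2. The mean log2 signal of this list was 8.62 on NSP replicate 3 and 7.94 and 7.75 on NSP replicates 1 and 2, and without NSP replicate 3 the median was 0.44 (camera adjusted p = 0.143), against 0.095 without NSP replicate 2 and 0.09 without SP replicate 3.

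In the stress-related lists 0 genes passed over all probe sets. The 25 hypoxia and glycolysis genes had a median of −0.0017 (camera adjusted p = 0.697), and 1 fell adjusted over the list alone, ANKRD37, from 236.9 ± 38.2 in NSP to 118.1 ± 2.83 in SP cells. The 25 endoplasmic reticulum and integrated stress genes had a median of −0.08 (camera adjusted p = 0.538) and 0.16 without NSP replicate 3, with DDIT4, an inhibitor of mTORC1, at 1.40 ± 0.36 (limma adjusted p = 0.194). The 14 heat shock genes had a median of −0.13 (camera adjusted p = 0.128), and −0.27 without NSP replicate 3 (camera adjusted p = 0.0113, but adjusted p = 0.604 with an estimated correlation). The 16 NRF2 and AHR target genes had a median of −0.06 (camera adjusted p = 0.538), with the AHR repressor AHRR at 0.81 ± 0.22. The 27 interferon-stimulated genes had a median of 0.03 (camera adjusted p = 0.595), and IRF9, an interferon-responsive transcription factor, was at 81.3 ± 12.4 in SP and 38.8 ± 10.6 in NSP cells. In the last 4 of these lists 0 genes passed adjusted over the list alone. Without SP replicate 3 the heat shock list passed (camera adjusted p = 0.0240), as did the endoplasmic reticulum list with a median of −0.34 (0.0147), but with all arrays adjusted p = 0.648 and 0.803 with an estimated correlation. The endoplasmic reticulum median was 0.11 without SP replicate 1, 0.14 without SP replicate 2, −0.18 without NSP replicate 1 and −0.24 without NSP replicate 2. With 1 array left out the heat shock median lay between −0.27 and −0.07, and the NRF2 and AHR median between −0.21 (without NSP replicate 1) and −0.0011 (without SP replicate 2). The interferon median then lay between 0.03 and 0.09 (without SP replicate 1 or 2), and the hypoxia median between −0.07 (without NSP replicate 1) and 0.05 (without SP replicate 1).

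Lists of cell identity and of abundant housekeeping transcripts had 0 members past either adjustment. The medians were 0.13 for 13 epithelial genes (camera adjusted p = 0.621), 0.08 for 9 luminal breast genes (0.776), −0.11 for 6 blood cell markers (0.621), 0.33 for 10 histone genes (0.0913) and −0.07 for 49 ribosomal protein genes (0.0837). KRT19, a simple epithelial keratin, was at 539.9 ± 184.9 in SP and 194.9 ± 169.3 in NSP cells (1.79 ± 0.66, limma adjusted p = 0.350). Its signal was 30.5 on NSP replicate 3 against 185.4 and 368.7 on NSP replicates 1 and 2, so the size of this difference leaned on that array. The blood cell markers stayed near background, PTPRC at 51.1 and 46.1 and HBB at 52.6 and 57.0 in SP and NSP cells. The histone list passed without NSP replicate 3, with a median of 0.31 (camera adjusted p = 0.0150, but adjusted p = 0.548 with an estimated correlation), and without SP replicate 3, with 0.53 (0.0147), but its median was 0.095 without SP replicate 1 (0.442). The ribosomal list passed without NSP replicate 1, with a median of −0.21 (0.00016), and without SP replicate 3, with −0.17 (0.00103), but turned to 0.05 without NSP replicate 3 and 0.01 without SP replicate 2, with adjusted p = 0.799 with an estimated correlation over all arrays. With 1 array left out the luminal median turned to −0.07 without NSP replicate 3 and was 0.28 without SP replicate 3. The blood marker median was −0.04 without NSP replicate 3, −0.02 without SP replicate 3 and 0.04 without SP replicate 1. The epithelial median lay between 0.08 (without SP replicate 3 or NSP replicate 3) and 0.22 (without NSP replicate 2). With all arrays it turned to −0.03 with no filter and to −0.02 without cross-hybridising probe set types. The sign of the median turned for the interferon, hypoxia, mesenchymal and ribosomal lists after quantile normalization, and for the interferon and luminal lists after median centring.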

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

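The control probe sets described here were examined only after the main results had been seen, and a minimum of 1.5-fold was set for naming one. Of the 13 human control probe sets looked at, none of which entered the test of genes, 1 had all SP arrays above all NSP arrays by at least that fold. The probe set for the 3' part of 18S ribosomal RNA was 2.02-fold higher in SP cells, at 1658 ± 257.2 (SD, n = 3) against 820.9 ± 16.2. Its middle and 5' probe sets were 1.15-fold and 1.22-fold higher, with overlapping groups. The control for 28S ribosomal RNA lay the other way, at 0.93-fold, 0.84-fold and 0.74-fold for its 5', middle and 3' probe sets, with no overlap for the middle one. The two-sided exact permutation p of the 3' probe set was 0.1, the smallest that 3 against 3 arrays allow.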

How the results depend on the processing

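The fits without both arrays of replicate number 3 and with the GAPDH ratio as a covariate were chosen after the data had been seen; the other alternatives were planned. All results are limma counts at an adjusted p under 0.05 unless said otherwise, and where a count or call changed, the cause was not tested. Against 39 changed probe sets, all higher, and 10 genes, the counts stayed within 1.5 times with pseudocounts of 1 and 64 (34 and 57, the latter with 1 lower), a robust variance prior (37) and a minimum of 2-fold (39). With no filter 0 probe sets and 0 genes passed (4698 probe sets at an unadjusted p under 0.05), and with no variance trend 0 and 0 (3046). SOX17 kept its log2 fold change of 1.60 in both but not its call (adjusted p = 0.0570 and 0.0625). The upper 25% of probe sets gave 22, all higher. Quantile normalization gave 17, all higher, 6 genes and 2 lists. Median centring gave 7, all higher, and 2 genes, with SOX17 at 1.48 (adjusted p = 0.0670). Without cross-hybridising probe set types there were 68 (66 higher, 2 lower) and 22 genes. At an adjusted p under 0.10 there were 123 (121 higher, 2 lower) and 30 genes. The mean of a gene's probe sets gave 2 genes, with SOX17 at 1.70 (adjusted p = 0.161). Leaving out 1 array at a time gave 0 to 239 probe sets, 0 to 209 higher, 0 to 30 lower, 0 to 98 genes and 3 (without NSP replicate 2) to 11 (without SP replicate 3) lists. The counts of 0, from leaving out NSP replicate 1, NSP replicate 2, SP replicate 1 or SP replicate 2, stood beside 2547, 2822, 1907 and 2130 probe sets at an unadjusted p under 0.05. SOX17 then lay between 1.49 and 1.74, and its adjusted p between 0.00937 (without NSP replicate 3) and 0.367 (without SP replicate 1). Without both arrays of replicate number 3 there were 1509 probe sets (1070 higher, 439 lower) and 739 genes, and with the GAPDH ratio as a covariate 259 (244 higher, 15 lower) and 97 genes. Against 6 lists called, 0 of the 25 passed with an estimated correlation and 0 with fry (1 and 9 of the 25 at an unadjusted p under 0.05). The G2/M list had a median of −0.74 without NSP replicate 3 and turned to 0.17 without SP replicate 3 (camera adjusted p = 0.551, with a range of 6.07e-08 to 0.868 over its alternatives). Both arrays of replicate number 3 were low for this list, so leaving out 1 of them weighs on 1 group only. The log2 difference in the GAPDH ratio, −0.36 with all arrays, lay between −0.76 and 0.34 with 1 array left out.

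No label ties the replicate number to a passage, so same-numbered SP and NSP arrays were not treated as pairs. Since the cells of each passage were sorted into both fractions, they may come from 1 sort, and whether they do is not known. Deviations from the group means correlated at 0.16, 0.09 and 0.28 for numbers 1, 2 and 3, and NSP replicate 1 correlated better with SP replicate 2, at 0.19, than with its own number. NSP replicate 3 went the other way, as its log2 signals correlated best with SP replicate 3, at 0.930. They correlated at 0.927 and 0.912 with NSP replicates 1 and 2. Any part shared by same-numbered arrays stays in the spread of the fit without a block. With the replicate number as a block 88 probe sets (86 higher, 2 lower) and 20 genes passed, all 39 of the fit without it among them, and the 6 lists were called as before.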

Other observations

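The tests on NSP replicate 3, on RNA quality of the NSP arrays, on scaling at an unadjusted p under 0.05 and on probe sets without a gene name were chosen after the results had been seen, as were the genes named in the next paragraph. Leaving out 1 array was planned, but its use to weigh the explanations of the last paragraph was chosen afterwards. A comparison of fold change with gene length was also made and is not reported, because no genome build is named for these arrays.

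Many of the 39 changed probe sets were not the brightest of their gene. A probe set without a gene name made up 17 of the 39, 43.6% against 14.9% of the tested probe sets with 1 symbol or none, an odds ratio of 4.41 (95% interval 2.20 to 8.71, two-sided Fisher's exact p = 1.67e-05; probe sets are not independent). Besides the 10 changed genes, 11 genes had a changed probe set that was dimmer than another of the same gene, and in 9 of these the brightest one showed less than 50% of its log2 fold change. These 11 genes were picked because the brightest probe set was not called, so a smaller change there is partly built in. Over all 5823 genes with 2 or more tested probe sets, the dimmest had the higher log2 fold change in 50.5%. For UGP2, an enzyme of UDP-glucose synthesis, the dim probe set gave 1.43 ± 0.21 and the brightest −0.33. For PGAP1, which remodels GPI anchors, the values were 1.59 ± 0.19 and −0.06, and for PSMG4, a proteasome assembly chaperone, 1.87 ± 0.25 and −0.17. The changed probe set of HNRNPDL, an RNA-binding protein, gave 1.82 ± 0.22 against 0.36, that of the transcription elongation factor AFF4 1.57 ± 0.22 against 0.38, and that of the corepressor CBFA2T2 2.27 ± 0.27 against 0.66.

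All 39 changed probe sets were higher in SP cells. Without NSP replicate 3, 87.4% of the changed probe sets were higher (209 higher, 30 lower), against bounds written after the result. This argues against RNA degradation on that array as the only source of the excess of higher ones. The absence of lower ones did depend on the arrays used, since without both arrays of replicate number 3 there were 1070 higher and 439 lower. The share at an unadjusted p under 0.05 went from 72.8% to 61.5% without NSP replicate 3. More probe sets then passed in both directions (2848 higher against 2240, 1780 lower against 835), which decides nothing. Degradation on the NSP arrays as a whole is argued against, as 2 of the 3 NSP arrays had GAPDH and ACTB ratios below those of all SP arrays. The authors' array scaling does not account for the direction of the strongest differences, those at an unadjusted p under 0.001. Of these, 97.1% were higher as deposited, 92.6% after quantile normalization and 86.5% after median centring. The number of calls did depend on the scaling, as the 39 changed probe sets became 17 and 7. At an unadjusted p under 0.05 the share of 45.2% after median centring was set by that step, so the source of the wider excess was not tested. The 10 ways to divide 6 arrays into 3 and 3 are too few for a share under 0.05; the real one gave 39 changed probe sets, 1 of 10 with as many, and the highest other gave 0 (2127 at an unadjusted p under 0.05). A difference between the cell fractions themselves stays open as a hypothesis.

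Immediate-early and short-lived transcripts moved both ways, with 9 higher and 5 lower in SP cells adjusted over the list alone, and their upward median of 0.21 did not pass (camera adjusted p = 0.0858). Stress of sorting that raises heat shock genes along with them is argued against by the heat shock median of −0.13 on the log2 scale, which lay between −0.27 and −0.07 with 1 array left out. A different share of cell cycle phases in the gate stays open: the G1/S median of −0.39 exceeded the size of 0.2 set beforehand, but it was −0.19 without NSP replicate 1, and the G2/M median changed sign without SP replicate 3. Both arrays of replicate number 3 were low for the G2/M list, so leaving out 1 of them weighs on 1 group only. Between same-numbered arrays the G2/M median was −0.42, −0.16 and −0.31 for numbers 1, 2 and 3. The G1/S median was −0.60, −0.49 and 0.05. NSP cells hold a DNA-binding dye, and lower RNA synthesis in them might leave fewer short-lived and unspliced transcripts; the median log2 fold change of probe sets without a gene name exceeded that of named ones of similar signal by 0.051, which lies between 0 and the 0.1 set as the bound. Within 5823 genes the dimmest probe set exceeded the brightest by a median of 0.0048, and by −0.06 to 0.03 with 1 array left out, so these arrays do not settle that hypothesis.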
